A study of Mus musculus with 6 samples.

How the data were processed

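Polyadenylated RNA was sequenced from colonic epithelial organoids, which are cultures that crypt cells form in a gel matrix, grown from 3 wildtype (WT) mice and 3 mice lacking Tnfr1 (KO). All 6 libraries were taken at day 7 after passage, and each library is a separate mouse per the labels. Per the labels' protocols, strand-keeping mRNA libraries were sequenced from 1 end.

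The authors deposited 1 table of transcript abundances in TPM (transcript shares scaled to a fixed total per library), with 1 column per library. Per the submitters' processing notes CASAVA, kallisto and sleuth were used with the genome build mm10. Their versions and the annotation release are not given in the sources used here. Per the file headers, the table also holds the authors' p-value and q-value, test statistic (a score) and variance terms per transcript, and a mean log estimated count. That mean is taken to be on the natural log scale. The deposited variance followed the variance of the natural log of TPM over 909 abundant transcripts (rank correlation 0.999). A rank correlation is the same for any log base, so this does not show the base. The TPM values were checked against transcript length in GENCODE M21. The log estimated count minus the natural log of TPM rose with length over the same transcripts (rank correlation 0.998), which TPM requires. With another base for the count this difference would also depend on abundance, so the value speaks for the natural log.

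The table lists only transcripts that its APPRIS column calls principal. The deposited columns therefore sum to 566626 to 653487 TPM, less than a full library, and isoforms outside this set are not analysed here. A TPM value is a share, so a rise of abundant transcripts lowers all others. kallisto divides reads that fit several transcripts among them, so related genes and isoforms can exchange signal. An exact 0 can be such a division and not an absence, since transcripts of widely used genes are also listed at 0 in some libraries.

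TPM keeps no sequencing depth, so the depth per library is unknown and no counting interval is given. The authors' mean log estimated counts give some idea of it: over the 13540 transcripts with a p-value, the estimated count had a median of 112 (quartiles 27.1 and 325). A transcript near the lower quartile is measured with few reads, so small differences there may have gone undetected. Detection by abundance was not tested.

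The 29373 rows held 385 repeats of a transcript with identical values, which were dropped. The 28988 transcripts were summed to 22420 genes, of which 4621 had more than 1 listed transcript. All gene IDs were found in GENCODE M21 (mm10 coordinates), which gave gene positions.

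A test on estimated counts had been planned. Because the values are TPM, the planned replacement was used: limma 3.58.1 (trend and robust options) in R 4.3.3 on log2(TPM + 1), over genes with at least 1 TPM in at least 3 libraries, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. This left 10431 genes. Fold changes are differences on the log2(TPM + 1) scale, which understates the change of genes with low values. The target gene was also given an exact permutation test. For 30 gene lists, limma's camera was run with a preset correlation of 0.01 over the 27 lists with at least 4 tested members. The target gene was left out of every list, and 8 of the lists' entries had no match in the table. A list score is the mean of log2(TPM + 1) over the members of the list, each centred on its mean over the 6 libraries. Genes within 10 Mb of the target were compared with the other genes by Fisher's exact test. The gene test was tried on simulated values with the real means and spreads for the comparison of KO and WT (10431 genes, 50 changed per size). It recovered 62% of changes of 2-fold, 80% of 4-fold, 96% of 8-fold and 100% of 16-fold, and called 7 unchanged genes. Changes were placed only in genes with a mean log2(TPM + 1) above 3, and errors were independent between genes. Recovery in genes with lower values, or where libraries share structure, was not measured. The adjusted threshold is also easier to reach when many genes change, and 200 were changed in this simulation. Recovery with fewer changed genes may be lower and was not measured either.

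The comparison, tests, lists and rule for named genes were fixed before the data were examined. The rule names the target, up to 10 genes per direction with the largest change among those past the adjusted threshold without overlap of the groups, or, failing that, the 5 with the smallest p in that direction as genes that did not pass, and up to 4 members per list with the smallest p. Gene names ending in Rik or made of Gm and a number were left out.

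Alternatives tried were median-ratio scaling, no filter, log2(TPM + 0.1), tests per transcript, a replicate block, leaving out each library, a correlation estimated per list, the self-contained test fry, and windows of 5 and 20 Mb. Added after the data were seen were a filter at 5 TPM, leaving out the KO libraries with Y-linked transcripts, a term for those transcripts, removal of the 13 mitochondrially encoded genes with rescaling, and a count of genes near the target at an unadjusted p. Figures were drawn with matplotlib 3.10.9.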

Results

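The series holds 6 libraries of mouse colonic epithelial organoids at day 7 after passage, 3 from WT mice and 3 from mice lacking Tnfr1, the main receptor for the inflammatory cytokine tumour necrosis factor. It asks how loss of the receptor changes gene expression in the epithelium. Between 10148 and 10345 genes per library reached 1 TPM. Values below are means ± SD over n = 3 libraries per genotype unless stated otherwise. Transcripts of the Y chromosome were found in KO replicates 2 and 3 (Eif2s3y at 19.7 and 23.7 TPM) and were listed at 0 in the other 4 libraries for this gene. Below, libraries with Y-linked transcripts are those with Eif2s3y at 1 TPM or more. Mitochondrially encoded transcripts made up 20.8% and 19.4% of the listed TPM in those libraries, 14.5% in KO replicate 1, and 10.6% to 15.4% in the WT libraries.

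Transcripts of the targeted gene were lower in every KO library. Tnfrsf1a (ENSMUSG00000030341, chromosome 6, 125349362 to 125362484, plus strand, mm10) measured 49.2 ± 7.82 TPM in WT and 17.9 ± 1.91 TPM in KO organoids. The KO libraries lay at 16.9, 16.7 and 20.1 TPM, and the lowest WT library at 41.0 TPM. The KO mean was 0.364 of the WT mean, and the log2 difference was -1.40 (SE 0.15). The listed transcripts thus remained measurable in KO organoids. Which part of the gene the allele removes is not given in the sources used here. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The adjusted p over all genes with limma was 0.158, and in the authors' deposited table the transcript had p = 2.92e-05 and q = 0.304.

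**Figure D1:**
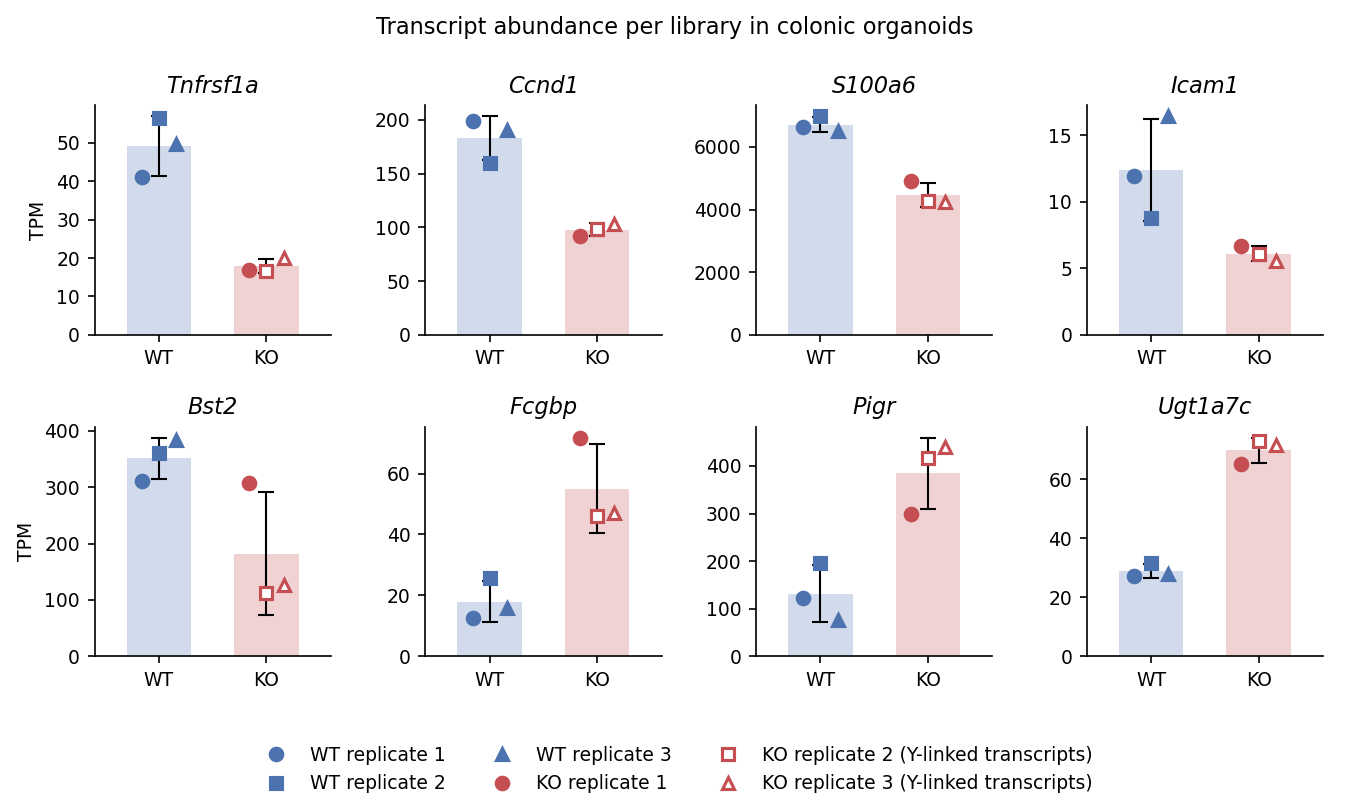
TPM (vertical axis, linear, from 0) of 8 genes in WT and KO organoids. Bars are means, error bars the SD of n = 3 libraries, and points single libraries, with open points for the KO libraries that carry Y-linked transcripts. Tnfrsf1a was at 16.7 to 20.1 TPM in KO and at 41.0 TPM or more in WT libraries, while Bst2 in KO replicate 1 (307 TPM) was close to WT replicate 1 (312 TPM).

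No gene passed the adjusted threshold when all genes were tested. Of the genes with the smallest p that were higher in KO organoids, Ugt1a7c, a glucuronosyltransferase that conjugates xenobiotics, measured 28.9 ± 2.43 TPM in WT and 69.8 ± 4.27 TPM in KO (ratio of means 2.42, adjusted p = 0.0841 with limma). Its neighbour Ugt1a6a, which shares exons with it so that reads can pass between them, went from 15.2 ± 3.83 to 40.3 ± 3.91 TPM. The aminopeptidase Xpnpep2 measured 0.390 ± 0.243 TPM in WT and 4.28 ± 1.25 TPM in KO, and Nxpe4 3.14 ± 0.546 and 9.33 ± 1.54 TPM. B4galnt3, a glycosyltransferase, was listed at 0 or almost 0 in all WT libraries and at 9.23, 3.19 and 7.32 TPM in KO replicates 1, 2 and 3.

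Among those lower in KO organoids, the F-box gene Fbxo36 was listed at 6.67, 12.7 and 14.9 TPM in WT replicates 1, 2 and 3 and at 0 in all KO libraries (adjusted p = 0.0841). Uxt was listed at 1.94, 2.08 and 2.77 TPM in WT and at 0 in all KO libraries. Pdlim4, which binds the actin cytoskeleton, measured 16.3 ± 0.856 TPM in WT and 6.38 ± 1.03 TPM in KO, and the DNA repair gene Trp53bp1 3.75 ± 1.19 and 0.1004 ± 0.107 TPM. None of these 9 genes passed. Fbxo36, Uxt, Trp53bp1 and B4galnt3 are each listed with 1 transcript. A shift to or from an isoform that is not listed therefore cannot be told apart from a change of the whole gene.

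In limma's test 0 of 10431 genes reached an adjusted p under 0.05, and the lowest was 0.0841. At an unadjusted p under 0.05 there were 1479 genes (14.2%), 733 higher and 746 lower in KO. Leaving out 1 library moved this count to 825 without WT replicate 3, 848 without KO replicate 3, 881 without KO replicate 2 and 2468 without WT replicate 2, and removing mitochondrial genes gave 1079 higher and 515 lower. The authors' deposited table held 0 transcripts with q under 0.05 and 1389 (10.3%) with p under 0.05. The count past the adjusted threshold rose to 59 without WT replicate 2, to 22 without KO replicate 1 and to 1 without WT replicate 1. Genes with no overlap between KO and WT libraries made up 19.6%, where chance gives 10% on average over splits. Genes move together and this share was not computed for other splits of the libraries, so an excess cannot be judged.

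Transcripts of the fetal-like and regenerative programme, which intestinal epithelium switches on during repair, were lower in KO organoids in 19 of 19 tested genes. The mean log2 difference was -0.86, 16 members were lower with p adjusted over the list alone and 0 when adjusted over all genes, and every KO library scored below every WT library. S100a6, a calcium-binding protein, measured 6709 ± 247 TPM in WT and 4475 ± 380 TPM in KO. The alarmin Il33 measured 11.6 ± 2.72 and 5.76 ± 0.0427 TPM, and Tnfrsf12a, the receptor for the cytokine TWEAK, 122 ± 5.30 and 87.5 ± 7.79 TPM. Camera called the list lower (adjusted p = 3.38e-11), and fry called it too (adjusted p = 0.0263), the only list that fry called. The call was lost with an estimated correlation (adjusted p = 0.171).

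Targets of NF-kB, the transcription factor that the receptor activates, were lower in 22 of 28 tested genes. The mean log2 difference was -0.61, and 10 members were lower when adjusted over the list alone and 0 over all genes. Ier3 measured 191 ± 45.1 TPM in WT and 103 ± 12.2 TPM in KO. The adhesion molecule Icam1 measured 12.4 ± 3.82 and 6.09 ± 0.561 TPM, the protease Plau (urokinase) 16.02 ± 4.96 and 7.85 ± 1.01 TPM, and Tnfaip2 3.11 ± 0.892 and 1.22 ± 0.193 TPM. Without WT replicate 3 the mean was -0.41. Camera called the list lower (adjusted p = 2.98e-05), but not with an estimated correlation (adjusted p = 0.528). Components of TNF receptor signalling, a list that also holds related receptors, were not called (12 of 28 tested genes higher and 16 lower, adjusted p = 0.121, and 0.528 with an estimated correlation). Of these, the TRAIL receptor gene Tnfrsf10b measured 21.6 ± 1.66 and 16.3 ± 0.589 TPM, the effector kinase Ripk3 129 ± 20.7 and 95.4 ± 9.19 TPM and Casp8 175 ± 44.0 and 115 ± 10.6 TPM.

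Markers of fibroblasts and muscle, cells that crypt cultures can carry along, moved the same way in 10 of 11 tested genes (mean log2 difference -1.11). 4 were lower when adjusted over the list alone and 0 over all genes. Dcn, a matrix proteoglycan, measured 98.6 ± 58.2 TPM in WT and 18.96 ± 4.11 TPM in KO, Vim 20.7 ± 5.64 and 6.39 ± 2.70 TPM, and Pdgfra 2.58 ± 0.544 and 0.980 ± 0.0607 TPM. Camera called the list lower (adjusted p = 2.14e-05), but not with an estimated correlation (adjusted p = 0.528). Of the 18 genes of the immune cell list only 2 could be tested, so the list was not. The others, macrophage genes such as Adgre1 and Itgam among them, did not reach 1 TPM in 3 libraries. The 2 genes therefore do not show a change in immune cells, and an adjustment over 2 genes is slight. Both tested genes were lower when adjusted over the list alone: the macrophage genes Cd68 (18.97 ± 1.08 and 12.1 ± 1.54 TPM) and Csf1r (2.86 ± 1.08 and 1.16 ± 0.248 TPM, close to the filter). Of the endothelial and neural list 1 gene could be tested, Esam, at 0.934 ± 0.424 TPM in WT and 0.702 ± 0.367 TPM in KO.

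Heat shock genes were lower in 15 of 16 tested genes (mean log2 difference -0.39), with 1 lower when adjusted over the list alone and 0 over all genes. This was Cryab, a small chaperone, at 17.3 ± 5.52 TPM in WT and 5.43 ± 1.82 TPM in KO. Hspb1, of the same family, measured 23.1 ± 4.22 and 13.2 ± 2.99 TPM. The list was called lower (adjusted p = 1.97e-04), but not with an estimated correlation (adjusted p = 0.528).

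Goblet cell genes, which serve mucus production, were higher in KO organoids in 15 of 16 tested genes (mean log2 difference 0.57). 1 was higher when adjusted over the list alone and 0 over all genes. This was Fcgbp, a mucus protein, at 17.9 ± 6.84 TPM in WT and 55.0 ± 14.6 TPM in KO. The transcription factor Creb3l1 measured 26.0 ± 5.45 and 47.8 ± 12.8 TPM, Klk1 28.6 ± 14.2 and 66.7 ± 10.4 TPM, and Spink4 817 ± 155 and 1207 ± 148 TPM. Genes of hypoxia and glycolysis were higher in 21 of 21 tested genes with smaller differences (mean log2 difference 0.39, and 0.18 without WT replicate 3, with 0 passing over the list alone or over all genes). The hexokinase Hk2 measured 31.5 ± 0.752 and 40.7 ± 2.54 TPM, and Ero1l, an oxidase of the endoplasmic reticulum, 154 ± 49.8 and 248 ± 20.8 TPM. Camera called both lists higher (adjusted p = 5.16e-05 for goblet cells and 3.63e-05 for hypoxia), but neither with an estimated correlation (adjusted p = 0.528 for each).

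In these 6 lists every KO library scored beyond every WT library on the same side. Of the 27 tested lists 8 separated in this way, where chance gives 10% on average over splits. They include the ErbB list and the Paneth cell and antimicrobial list, which camera did not call. Lists can move together, so an excess cannot be judged. In the 7 other lists that camera called, KO replicate 1 scored within the range of the WT libraries, and KO replicates 2 and 3, the libraries with Y-linked transcripts, lay further out. When those 2 libraries were left out together, KO replicate 1 was the only KO library left to test. Its scores had set the 6 lists apart from the 7, so calls made there are no separate check. The size that remained differed among the 7. The mean log2 difference went from 0.69 to 0.43 for small intestine identity, from 0.34 to 0.23 for fatty acid oxidation, from 0.51 to 0.24 for absorptive colonocytes, from 0.57 to 0.13 for xenobiotic metabolism and from -0.23 to -0.070 for Wnt targets. It was close to 0 for interferon response and of the opposite sign for cell cycle, as given below. Single members also differed in KO replicate 1: Slc5a1 (53.8 TPM), Cpt1a (36.6 TPM), Gsta3 (46.2 TPM) and Guca2a (69.2 TPM) lay above every WT library there.

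Interferon response genes showed the widest gap of this kind. All 30 tested genes were lower on average in KO organoids (mean log2 difference -1.22), with 0 passing over the list alone or over all genes. Irf7, an inducer of interferons, measured 218 TPM in KO replicate 1, 85.0 and 80.5 TPM in KO replicates 2 and 3, and 253 ± 48.3 TPM in WT. Bst2, an antiviral membrane protein, measured 307, 111 and 127 TPM in KO replicates 1, 2 and 3 and 352 ± 36.4 TPM in WT. The immunoproteasome subunit Psmb8 measured 16.5 ± 4.82 TPM in WT and 7.49 ± 2.91 TPM in KO. Camera called the list lower (adjusted p = 3.12e-10), but not with an estimated correlation (adjusted p = 0.528). Without KO replicates 2 and 3 the mean log2 difference was -0.074 (adjusted p = 0.490).

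Cell cycle genes were also lower on average in 30 of 30 tested genes, with 0 passing over the list alone or over all genes. The mean log2 difference was -0.35, and -0.57 without KO replicate 1. Cdk1, the kinase that starts mitosis, measured 88.3 TPM in KO replicate 1, 65.8 and 66.4 TPM in KO replicates 2 and 3, and 100.3 ± 12.8 TPM in WT. The list was called lower (adjusted p = 5.16e-05), but not with an estimated correlation (adjusted p = 0.608), and its mean turned to 0.095 without KO replicates 2 and 3. Wnt target genes were lower in 9 of 13 (mean log2 difference -0.23, adjusted p = 0.0427, and 0.528 with an estimated correlation), with 2 lower over the list alone and 0 over all genes. These were the cyclin Ccnd1, at 183 ± 20.4 TPM in WT and 97.9 ± 5.68 TPM in KO, and the transcription factor Tcf7, at 13.3 ± 2.10 and 8.14 ± 0.813 TPM. Both were lower in every KO library, KO replicate 1 included (91.9 and 8.80 TPM). The Wnt call by camera was lost without WT replicate 1 (mean -0.11, adjusted p = 0.334), without KO replicate 2 (0.0797) and without KO replicate 3 (0.0871). It was also lost with a replicate block (0.137) and at a filter of 5 TPM (0.136). The mean was -0.35 without WT replicate 2.

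Absorptive colonocyte genes were higher in 22 of 27 (mean log2 difference 0.51, and 0.78 without WT replicate 2, with 0 passing over the list alone or over all genes). The anion exchanger Slc26a3 measured 26.7 TPM in KO replicate 1, 76.2 and 83.3 TPM in KO replicates 2 and 3, and 23.2 ± 1.34 TPM in WT. Guca2a, the precursor of the hormone guanylin, measured 41.2 ± 15.8 and 70.0 ± 1.35 TPM, whereas Clca4b was lower, at 17.9 ± 5.44 and 9.61 ± 3.06 TPM. Fatty acid oxidation and PPAR targets were higher in 13 of 15 (mean log2 difference 0.34, 0 passing over either), among them Cpt1a, which brings fatty acids into mitochondria, at 25.4 ± 4.14 and 36.3 ± 1.69 TPM. The dehydrogenase Acadl went the other way, at 230.5 ± 58.3 and 141 ± 22.01 TPM. Genes of xenobiotic metabolism and redox balance were higher in 15 of 19 (mean log2 difference 0.57). Over the list alone 2 were higher, the glutathione transferases Gstm1 (31.3 ± 9.58 and 78.3 ± 14.3 TPM) and Gsta3 (22.2 ± 7.79 and 44.6 ± 3.11 TPM), and 1 lower, the haem oxygenase Hmox1 (29.4 ± 4.40 and 17.4 ± 2.25 TPM). None passed over all genes. The small intestine identity list was higher in 6 of 6 (mean log2 difference 0.69), with 1 passing over the list alone and 0 over all genes. This was Slc5a1, a glucose transporter that colonic epithelium can also express, at 31.9 ± 11.3 and 57.8 ± 4.31 TPM.

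Camera called these 4 lists higher, with adjusted p = 0.00246 for absorptive colonocytes, 9.43e-04 for fatty acid oxidation, 0.00561 for xenobiotic metabolism and 0.0162 for small intestine identity. None held with an estimated correlation (adjusted p = 0.608 for absorptive colonocytes and 0.528 for the others). Without WT replicate 1 the calls for absorptive colonocytes (adjusted p = 0.183) and small intestine identity (adjusted p = 0.0564) were lost.

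**Figure D2:**
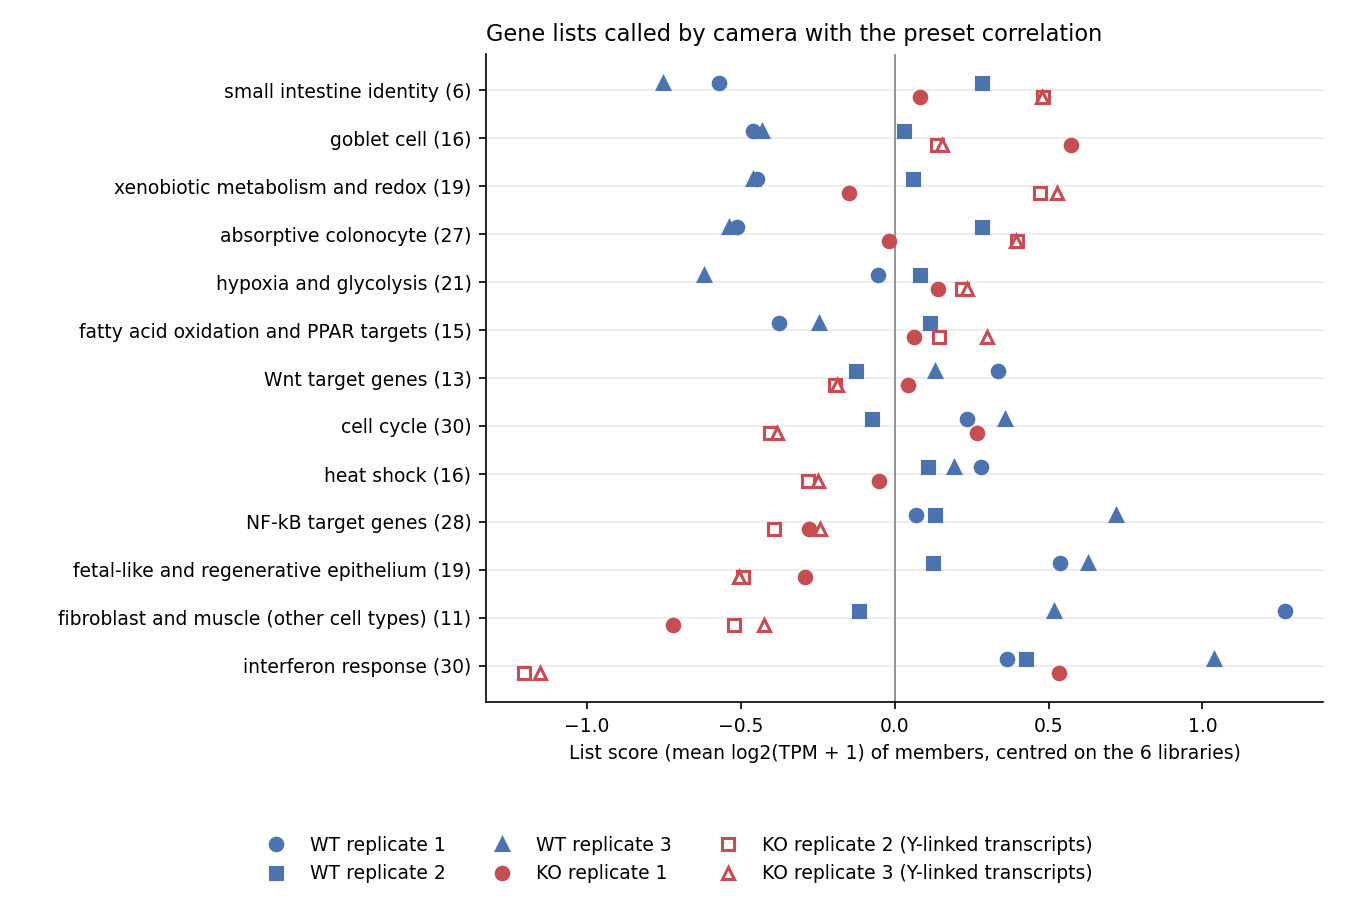
Scores per library (horizontal axis, log2 scale, centred on the 6 libraries) of the 13 gene lists that camera called, with the number of tested genes in brackets. Points are single libraries, WT above and KO below each line, and open points mark the KO libraries with Y-linked transcripts. KO replicate 1 lies below all WT libraries in the fetal-like list (-0.29 against 0.13 or more) and among them in the interferon list (0.53).

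Stem cell and secretory lists other than goblet cells were not called. The intestinal stem cell list had 7 genes higher and 10 lower (mean log2 difference -0.044, adjusted p = 0.598). Its member Lrig1 measured 21.1 ± 0.575 TPM in WT and 29.1 ± 4.001 TPM in KO, and Ascl2 10.8 ± 1.32 and 7.57 ± 1.34 TPM. The Notch pathway (8 higher, 4 lower, adjusted p = 0.327) included Dll4 at 2.86 ± 0.202 and 4.98 ± 0.865 TPM. The enteroendocrine list had a mean log2 difference of -0.0060 but a median of 0.12 and a direction of higher in the test (11 higher, 5 lower, adjusted p = 0.667). Its members went both ways: the hormone gene Insl5 measured 27.5 ± 1.59 TPM in WT and 48.7 ± 16.6 TPM in KO, the prohormone-processing gene Cpe 71.3 ± 26.96 and 36.6 ± 7.17 TPM, and the hormone gene Cck 32.2 ± 21.1 and 7.75 ± 5.74 TPM. The 4 tested tuft cell genes were split evenly (adjusted p = 0.860).

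The list of Paneth cell and antimicrobial genes was not called (adjusted p = 0.507), yet 4 of its 17 tested members passed over the list alone and 0 over all genes. Pigr, which carries antibodies across the epithelium, was higher at 131 ± 60.0 TPM in WT and 385 ± 74.7 TPM in KO, and the oxidase regulator Noxo1 at 4.99 ± 0.868 and 9.55 ± 1.29 TPM. The defensins Defa24 (13.7 ± 4.27 and 4.05 ± 2.58 TPM) and Defa17 (23.6, 4.41 and 17.3 TPM in WT, and 0, 0 and 4.03 TPM in KO) were lower. Defensins are a family of near-identical copies, so their values are uncertain.

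Of the remaining lists, cell junction genes (16 higher, 7 lower, adjusted p = 0.106) included the claudin Cldn8 at 14.5 ± 8.28 TPM in WT and 36.1 ± 5.43 TPM in KO. The cell junction call was made without WT replicate 2 (adjusted p = 0.00774) and once mitochondrial genes were removed (0.0339), both with the preset correlation. With an estimated correlation and all libraries the adjusted p was 0.608. Antigen presentation (3 higher, 9 lower, adjusted p = 0.197) was called lower without WT replicate 1 with the preset correlation (adjusted p = 0.00341, against 0.707 with an estimated correlation and all libraries), and B2m measured 2586 ± 661 and 1567 ± 362 TPM. ErbB receptors and ligands (3 higher, 6 lower, adjusted p = 0.246) included Areg at 361 ± 144 and 210.2 ± 13.6 TPM. Immediate early genes had a mean of -0.079, a median of 0.013 and a direction of lower (adjusted p = 0.733). The unfolded protein response (adjusted p = 0.567), distal colon identity (0.598), cholesterol synthesis (0.821) and cell death and p53 targets (0.934) were not called either.

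A knockout allele can carry neighbouring sequence from the strain in which it was made, so genes around the target were looked at separately. Of 106 tested genes within 10 Mb of Tnfrsf1a, 0 passed limma's adjusted threshold, as elsewhere, and 16 (15.1%) had an unadjusted p under 0.05. This count was 7 without WT replicate 3, 8 without WT replicate 1, 9 without KO replicate 2, 10 without KO replicate 3 and 27 without WT replicate 2, and 8 at a filter of 5 TPM or without KO replicates 2 and 3. Among the 10324 other genes this share was 14.2%. The odds ratio was 1.08 (95% confidence interval 0.589 to 1.85), and Fisher's exact test, two-sided, gave p = 0.779. Against the other 380 genes of chromosome 6 (16.6%) Fisher's exact test gave p = 0.768. The 16 genes include B4galnt3, named above, which lies 5.05 Mb from Tnfrsf1a. A comparison of shares does not bear on single genes, so whether neighbouring sequence underlies the difference in B4galnt3 was not tested.

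The first principal component held 44.6% of the variance and did not follow genotype alone. It placed WT replicates 1 and 3 at -31.1 and -39.4, KO replicate 1 and WT replicate 2 at 0.587 and 4.42, and KO replicates 2 and 3 at 33.6 and 31.9. Libraries of the same genotype correlated at 0.951 to 0.966 across genes, and libraries of different genotype at 0.917 to 0.962. Genes are not independent replicates, so these values only describe the libraries.

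**Figure D3:**
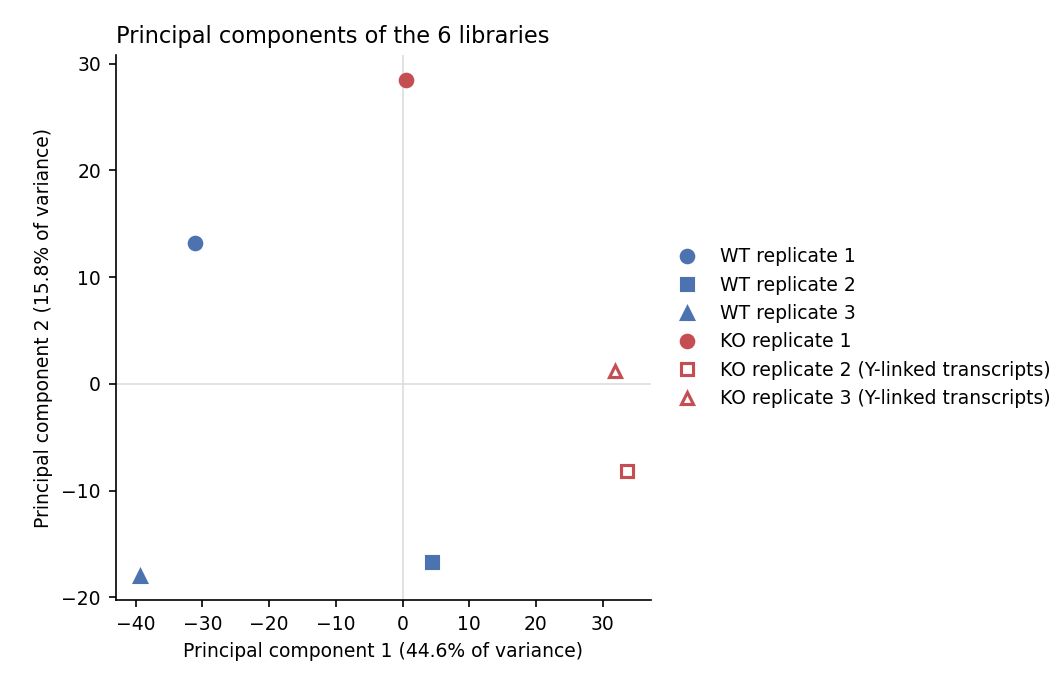
The 6 libraries on the first and second principal components of log2(TPM + 1) over the 10431 tested genes (44.6% and 15.8% of the variance). Each point is a library, and open points mark those with Y-linked transcripts, which lie at 33.6 and 31.9 on the horizontal axis, while KO replicate 1 and WT replicate 2 lie near its centre.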

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

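The tests of the Y-linked transcripts, of fibroblasts and of the mitochondrial share below were chosen after the data were seen. Eif2s3y, a translation factor gene on the Y chromosome, measured 19.7 and 23.7 TPM in KO replicates 2 and 3, and the RNA helicase gene Ddx3y 4.38 and 7.15 TPM. Both were listed at 0 in KO replicate 1 and in the WT libraries. They stood out because they lie outside the compared genes and above the WT level. The sex of the mice is not given in the sources used here. Every library with Eif2s3y and Ddx3y above 0 is a KO library, so their effect and that of genotype can be separated only through KO replicate 1.

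The lower interferon response genes were the first pattern weighed. KO replicate 1 scored -0.0745 from the WT mean (n = 1 library), while KO replicates 2 and 3 scored -1.21 and -1.15 against 0.36 or more in WT libraries. This is consistent with a difference that goes with the libraries carrying Y-linked transcripts and not with the genotype alone. Whether sex, the culture or another feature of those libraries underlies it was not tested. A larger mitochondrial share lowers all other TPM values. It is argued against as the whole cause, since the mean log2 difference was -1.23 with mitochondrial genes removed. The list was still called. Camera compares a list with the other genes, so a shift shared by all genes would not by itself undo a call.

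The lower fetal-like and regenerative genes were the second pattern. Removing mitochondrial genes left a mean log2 difference of -0.83, which argues against the mitochondrial share as the whole cause. The call remained too, but for the same reason as above it does not bear on this. More fibroblasts in the WT organoids stay open as a source. The summed TPM of the 4 most abundant members (S100a6, Ly6e, Anxa1 and Ly6a) differed by 5499 (SE 1170) between WT and KO, and that of the 11 tested fibroblast genes by 149 (SE 55.3), or 2.71% of it. For the 15 other members the share was 16.7%. The levels of these members in fibroblasts were not measured here, so a contribution of fibroblasts cannot be told apart from a change in the epithelium for either set. Several of the fibroblast genes can also be expressed by epithelium. KO replicate 1 scored -0.417 from the lowest WT library. As it is the only KO library with Eif2s3y and Ddx3y listed at 0, genotype and Y-linked transcripts cannot be told apart here. Loss of the receptor may lower this programme, a hypothesis that needs KO and WT mice matched for sex.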

How the results depend on the processing

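The filter at 5 TPM, the settings for Y-linked transcripts and mitochondrial genes, and the count near Tnfrsf1a at an unadjusted p were chosen after seeing the data. Planned fits on counts, their scaling and a filter on counts scaled by library size were not run, because the values are TPM. The cause was not tested for the changes below, except that settings with fewer libraries or genes have less to test.

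Tnfrsf1a stayed lower under all alternatives run, at -1.47 with either Y setting and from -1.52 to -1.29 when 1 library was left out. The number of genes past the adjusted threshold was 0 in 8 of 9 other settings, and 2 with mitochondrial genes removed. It ranged from 0 to 59 when 1 library was left out. At an unadjusted p under 0.05 it was 444 without the Y-positive KO libraries, 630 with the presence of Y-linked transcripts as a covariate, and 825 to 2468 when 1 library was left out (881 without KO replicate 2, 848 without KO replicate 3, 825 without WT replicate 3 and 2468 without WT replicate 2). Removing mitochondrial genes gave 1079 higher and 515 lower. Where leaving out libraries left 1 KO library, it is assumed to vary like the WT libraries.

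The number of called lists was 6 in both Y settings, 0 with the correlation estimated per list, 1 by fry, and 11 to 14 when 1 library was left out. The labels do not say whether same-numbered WT and KO libraries belong together, though the file headers give them a shared number. Deviations from the genotype mean correlated at 0.13, 0.20 and -0.12 between same-numbered libraries. With 3 libraries per genotype this cannot exclude a pairing. With a replicate block 0 genes passed and 12 lists were called, with the Wnt list lost (adjusted p = 0.137). At TPM of at least 5 the Wnt list was lost too (0.136). Near Tnfrsf1a at an unadjusted p the count was 8 at TPM of at least 5, 8 without the Y-positive KO libraries, 9 with the covariate, and 7 to 27 when 1 library was left out (9 without KO replicate 2, 10 without KO replicate 3, 8 without WT replicate 1, 7 without WT replicate 3 and 27 without WT replicate 2).

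These directions reversed. In both Y settings: cell cycle 0.095, antigen presentation 0.16, stem cell 0.22, Esam 0.15, H2-D1 0.011, H2-K1 0.038 and Notch2 0.11. At TPM of at least 5: Paneth cell and antimicrobial 0.011, and immediate early genes 0.019. For cell death and p53 targets the test's direction changed with fry and the replicate block (mean -0.077 in each) and with no filter (-0.051). Tuft cell changed with no filter (0.020).

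Leaving out 1 library reversed cell death (range -0.14 to -0.0010), cholesterol synthesis (-0.037 to 0.086), enteroendocrine cell (-0.18 to 0.19), immediate early (-0.15 to 0.014), stem cell (-0.18 to 0.060), tuft cell (-0.29 to -0.0089) and unfolded protein response (0.017 to 0.11), and Hoxd13 (-0.26 to 0.048), Hpgds (-0.0051 to 0.27) and Slc10a2 (-0.054 to 0.57). Where the range keeps 1 sign, the test's direction changed and not the mean.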

Other observations

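The gene families, the comparison of splits and the transcripts listed in 1 genotype below were looked at after the data were seen. Median-ratio scaling had been chosen before. Genes grouped by the letters of their symbols gave 270 families with at least 6 tested members. Camera called 23 of them with the preset correlation and 0 with an estimated correlation. The families' directions were not repeated under other scalings.

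Keratins, the filaments of epithelial cells, were among the families called lower in KO organoids (adjusted p = 0.00224, 15 genes). Krt36 measured 82.8 ± 29.3 TPM in WT and 25.6 ± 1.49 TPM in KO (mean ± SD, n = 3), and Krt14 53.5 ± 20.98 and 12.3 ± 5.05 TPM. Serpins of clade B, which inhibit proteases, were called lower too (adjusted p = 0.00162, 7 genes), with Serpinb11 at 15.1 ± 5.36 and 5.00 ± 0.366 TPM and Serpinb5 at 102 ± 20.7 and 60.4 ± 6.73 TPM. So were the matrix metalloproteinases (adjusted p = 0.00385, 9 genes), with Mmp10 at 132 ± 38.5 and 46.5 ± 2.61 TPM and Mmp3 at 185 ± 90.9 and 27.2 ± 2.84 TPM. The collagens, some of which are also among the fibroblast markers, had the smallest p of all families and were called lower (adjusted p = 6.99e-05, 12 genes, median log2 difference -0.86), with Col4a2 at 59.98 ± 5.28 and 36.1 ± 6.29 TPM. Metalloproteinases and collagens are both made by fibroblasts, so these 2 families moved together with markers of another cell type. Annexin Anxa5 measured 146 ± 19.003 and 85.3 ± 8.04 TPM. The family beginning with Ly included Ly6g at 739 ± 199 and 349 ± 15.7 TPM. In the keratins, clade B serpins, metalloproteinases and collagens each KO library scored below each WT library. None of these genes passed limma's adjusted threshold.

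Carboxylesterases, which hydrolyse drugs and lipids, were called higher (adjusted p = 6.99e-05, 10 genes). Ces2a measured 9.91 ± 5.24 TPM in WT and 32.7, 82.7 and 83.3 TPM in KO replicates 1, 2 and 3. The family's score was 0.027 in KO replicate 1, close to the highest WT library (-0.056), and 1.11 and 1.04 in KO replicates 2 and 3, so the libraries with Y-linked transcripts held most of the difference. Cytochromes P450 were called higher as well (adjusted p = 0.00224, 24 genes), with Cyp2c68 at 16.1 ± 7.77 and 48.4 ± 1.64 TPM. As a family they scored within the WT range (-0.75 to 0.099) in KO replicate 1 (-0.045) and above it in KO replicates 2 and 3 (0.68 and 0.65), the libraries with Y-linked transcripts.

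B4galnt3, a glycosyltransferase gene, lies on chromosome 6 at 5.05 Mb from Tnfrsf1a. A transcript of the ribosomal protein gene Rpl29 was listed at 0 in WT libraries and at 33.6, 68.3 and 111 TPM in KO replicates 1, 2 and 3, while the summed gene measured 1203 ± 175 TPM in WT and 1248 ± 103 TPM in KO. In all, 13 transcripts were at 2 TPM or more in each library of 1 genotype and under 0.05 TPM in each library of the other, 7 in KO and 6 in WT, and 1 of the 13 lies on chromosome 6. The highest count in another split of the libraries was 14, and 2 of the 10 splits had as many as genotype.

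Cell cycle and absorptive colonocyte genes also separated the libraries in another way. WT replicates 1 and 3 with KO replicate 1 against WT replicate 2 with KO replicates 2 and 3 gave 2467 genes at an unadjusted p under 0.05, against 1479 for genotype. In that split camera called 12 lists with the preset correlation, 10 of them also called for genotype. The split was picked for its number of genes, and an estimated correlation was not run for it. The cell cycle list was higher in the trio with WT replicates 1 and 3 (adjusted p = 5.05e-13), and absorptive colonocyte genes were lower (2.07e-08). Interferon response was called too (2.70e-09), but WT replicate 2 scored 0.43, above WT replicate 1 (0.36), so that list did not separate the trios. Fetal-like (adjusted p = 0.0153), hypoxia (8.12e-04) and heat shock genes (0.0148), whose scores separated the genotypes, were called in that split as well. Fibroblast (0.0832), NF-kB (0.133) and goblet cell genes (0.487), whose scores also separated the genotypes, were not called there. The fetal-like list did not separate the trios, since WT replicate 2 scored 0.13, above KO replicate 1 (-0.29). The listed TPM also divided the trios, at 592168 or less and 628638 or more. This points to a structure of the samples other than genotype. After median-ratio scaling that split gave 2483 genes and genotype 1498. The scaling factors lay between 0.999 and 1.03 and moved little, so this does not test unequal scaling, which was left open. No biological explanation was tested.

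With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of genes past the adjusted threshold was 0 for genotype and 4 in the highest other split. Any split has at least 0, so counting the splits with as many decides nothing for this number. At an unadjusted p under 0.05 the number of genes was 1479 and 2467, with 2 splits as large. The number of lists called with the preset correlation was 13 and 12, with 1 split as large, genotype itself. Every other split also called lists, 5 at the lowest, so a call with the preset correlation is not by itself evidence of an effect of genotype.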
